A study of Homo sapiens with 8 samples.

How the data were processed

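The study profiled 2 histone marks by ChIP-seq in DLD1, a human colorectal cancer cell line. The cells lacked USP7, a deubiquitinating enzyme, and carried a GFP-USP7 transgene under a doxycycline-responsive promoter. Per the labels, cells were left uninduced or were treated with 1 µg/ml doxycycline for 3 days, and chromatin was precipitated with antibodies against H2AK119ub1, the ubiquitin mark that PRC1 places on histone H2A, or H3K27me3, the methyl mark that PRC2 places on histone H3. Each of the 4 groups had 2 libraries, which the labels' protocols describe as biological duplicates. The labels name different H3K27me3 antibodies in different fields, so the supplier is left open here. Drosophila chromatin was added to each chromatin sample as an external reference, per the labels' protocols.

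The deposited table lists 45450 regions with the number of reads of each library in each region. Its counts were made by SICER peak calling and follow-up read counting, per the file headers. The submitters' processing notes also name Bowtie2, SAMtools, Picard, bedtools and deepTools and the hg19 build, without versions. Whether regions were called per library or on pooled libraries is not given in the sources used here. Whether the counts were adjusted to the Drosophila reads is also not given. The count columns held whole numbers with no gaps of the kind that scaling up and rounding leave. Scaling down and rounding would leave no gaps, nor would drawing a subset of reads to match the Drosophila reads. As 6 of the 8 library totals lay between 4295842 and 4665162 reads, an adjustment of either kind is not excluded. The majority direction of the H2AK119ub1 calls depends on this. The authors' deposited log2 columns were log2(count + 0.5) with no scaling between libraries, as a recalculation showed. Their fold changes are differences of the group means of these log2 values, and the p-values in the authors' deposited table match an equal-variance test of the same values, again without scaling. Per the file headers these group means are called "log2nc", which the sources do not spell out. The p column held text in place of a number at 9 regions for H2AK119ub1 and at 26 for H3K27me3. No region ended past an hg19 chromosome end, whereas 302 ended past a GRCh38 end, and all 45450 starts were multiples of 200. Coordinates are printed as the deposited table gives them, on hg19. No hg19 gene annotation was used here, so regions are named by position and carry no gene names. The planned tests of 16 gene lists were not run for that reason, and the fixed genes of the naming rule, USP7 among them, were not located.

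Counts were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test was two-sided with robust dispersion, regions with low counts were left out with filterByExpr (minimum count 10), and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Library sizes were scaled by TMM within each antibody. TMM sets the typical region to no change, so each change is relative to that region. The groups, the tests, the TMM scale for raw counts, the naming rule and most alternatives were fixed before the data were examined. The written plan gave another rule, no further scaling, for values that the authors had already normalised. The counts were taken as raw from their values, but this is not certain, and calls on both scales had been seen when that was settled. The deposited counts had first been taken as the main scale. The counts of calls in each comparison are therefore printed on both scales. On the deposited counts the median log2 change was 0.51 for H2AK119ub1 and −0.089 for H3K27me3, against −0.0058 and 0.0026 on the TMM scale.

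The 4 libraries of an antibody were fitted together, and the difference between the marks was an interaction term over all 8 libraries. Medians and region summaries used log2(scaled count + 1). The median change over all regions was taken on the deposited counts. An exact permutation test of the library medians of 2 against 2 libraries cannot give a two-sided p below 0.333. For each mark, the named regions were the 10 with the largest rise and the 10 with the largest fall among regions that passed the test. They also needed a group mean at or above the median of all regions, and both induced libraries on the same side of both uninduced ones. For the interaction, the 5 largest differences each way were named. Region classes, width and distance bins and the H2AK119ub1 density bins were chosen after seeing the data. A region was called dominated by a mark when the mean log2 count of that mark exceeded the other's by more than 1. Classes were first cut on all 8 libraries, which include those of the change, so part of the difference between classes was built in, and it ran from 0.31 to 1.21 over the 4 library pairs. They were therefore cut again on the uninduced H3K27me3 libraries and the uninduced H2AK119ub1 library outside each pair. For the density tilts, regions were likewise ranked in libraries outside the ratio. The overlap expected within bins of read number was also added after seeing the data. The H3K27me3 level of a region was its mean number of reads per kb. Chromosome lengths of hg19 came from GenomeInfoDb 1.38.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

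The fits were tested on simulated counts with 200 changed regions. On the TMM scale, the H2AK119ub1 fit over 40862 regions recovered 4 of 67 regions changed by 1.5-fold, 30 of 67 changed by 2-fold and 52 of 66 changed by 3-fold, and 4.44% of its calls were unchanged regions. For the H3K27me3 fit over 40147 regions these numbers were 12 of 67, 41 of 67 and 56 of 66, with 2.68% false calls. For the interaction over 44612 regions they were 2 of 67, 15 of 67 and 31 of 66, with 5.88% false calls. Changes of 1.5-fold were thus mostly missed in this simulation. It changed only 200 regions, against 9168 H2AK119ub1 calls in the data, so the adjusted p threshold was harder to pass for that mark. Its noise was also drawn independently for each region. The recovered shares and the shares of false calls may therefore not carry over to the data.

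Replicates were compared before they were averaged. The H3K27me3 uninduced libraries differed by little more than sampling noise over 43688 regions, with a chi-square per degree of freedom of 1.01. In the 104 regions with more than 5000 reads over both libraries the ratio was 2.87, so they were kept as 2 replicates, and a fit that counts them as 1 was added. Over all regions with enough reads, the ratio was 1.58 for H2AK119ub1 uninduced, 2.58 for H2AK119ub1 induced and 1.16 for H3K27me3 induced. In regions with more than 5000 reads it was 8.01, 30.7 and 11.9 in these groups. Alternatives changed the library scale, the test, the count filter, the pseudocount, the threshold, the replicate block and the libraries included. The counts as deposited, limma with trend, the crossed block, the averaged H3K27me3 libraries and the other definition of H3K27me3 level were added after seeing the data. limma 3.58.1 and DESeq2 1.42.0 were used for alternatives.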

Results

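H2AK119ub1 and H3K27me3 were profiled by ChIP-seq in USP7-deficient DLD1 cells, a human colorectal cancer line, without and with induction of a GFP-USP7 transgene. Each of the 4 groups had 2 libraries. The 45450 regions had a median width of 2600 bp and covered 374.0 Mb, or 12.1% of the hg19 chromosomes. The reads counted in these regions numbered 4611950 and 4464578 in the H2AK119ub1 uninduced libraries and 6859423 and 7654255 in the induced ones. The H3K27me3 libraries held 4610394 and 4582578 reads without induction and 4665162 and 4295842 with it. The mean H2AK119ub1 total was 1.60 times as large with induction as without, and the mean H3K27me3 total 0.975 times. Reads outside the regions and reads from the added Drosophila chromatin are not analysed here, so these totals are not the sequencing depth.

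All induced libraries had doxycycline and the uninduced ones had none, and no treated cells without the transgene were among the samples. An effect of doxycycline itself therefore cannot be told apart from that of GFP-USP7 in any comparison. The first comparison asked which regions gained or lost H2AK119ub1 when GFP-USP7 was induced. Relative to the typical region, H2AK119ub1 rose at 2777 and fell at 6391 of 41128 tested regions (edgeR, TMM scale, adjusted p under 0.05). The risen regions had a median log2 change of 0.62, or 1.54-fold, and the fallen ones −1.26, or 2.39-fold. On the counts as deposited, without library scaling, 18602 regions rose and 2976 fell of 41107. Which direction held the majority thus depended on the scale, while 0 regions were called in opposite directions on these scales. Under all 5 scales tried, 1316 regions were higher and 2976 were lower after induction. A library scale moves every region of a library by the same factor. These numbers therefore mostly reflect the strictest scale each way, total counts for rises (1324) and deposited counts for falls (2976). The agreement between scales and the 0 opposite calls were thus largely given in advance. The regions higher on every scale had a median width of 27600 bp, against 3200 bp over all tested regions, and 20.4% of them lay within 2 Mb of a chromosome end, against 4.49%. On the TMM scale, 1.89% of regions up to 1 kb wide and 34.8% of those over 50 kb were called as rises. The median log2 changes of these width bins were 0.041 and 0.30. A smaller change can pass in wide regions, which hold more reads, so the contrast in width was not separated from the power of the test.

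**Figure D1:**
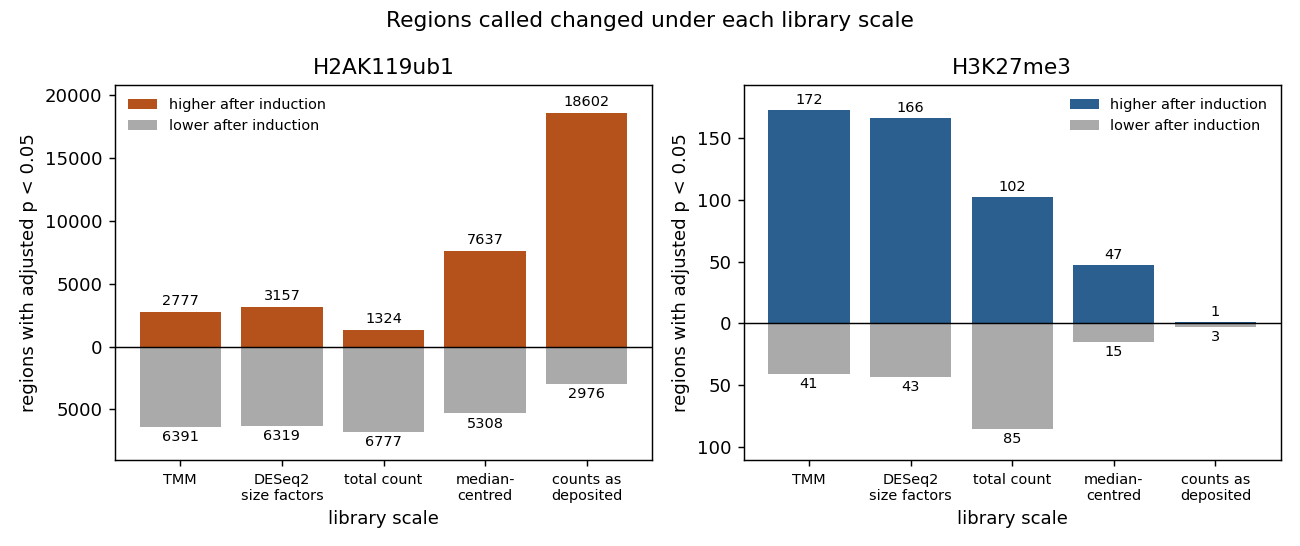
Number of regions with adjusted p under 0.05 (edgeR) on each library scale, H2AK119ub1 on the left and H3K27me3 on the right. Bars above 0 are regions higher after induction and bars below 0 are regions lower. For H2AK119ub1 the split is 2777 higher and 6391 lower on the TMM scale and 18602 higher and 2976 lower on the counts as deposited.

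The median region showed a log2 change in H2AK119ub1 of 0.51 on the deposited counts, or 1.42-fold, and 72.1% of regions were higher. It was −0.14 with total-count scaling and −0.0058 on the TMM scale. The library medians of log2(count + 1) were 5.19 ± 0.028 with induction and 4.86 ± 0 without (SD, n = 2 each). The exact two-sided permutation p of 0.333 is the smallest that 2 against 2 libraries can give.

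Whether the H2AK119ub1 response differed between kinds of region was not settled. Regions were classed by the uninduced libraries outside each pair of an induced and an uninduced library, so that no library entered both the class and the change. On the deposited counts, the median log2 change over the 4 pairs ran from 0.41 to 0.75 in regions dominated by H2AK119ub1 reads and from −0.068 to 0.47 in regions dominated by H3K27me3 reads. The difference between these classes ran from −0.067 to 0.81 and was below 0 in 1 of the 4 pairs.

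**Figure D2:**
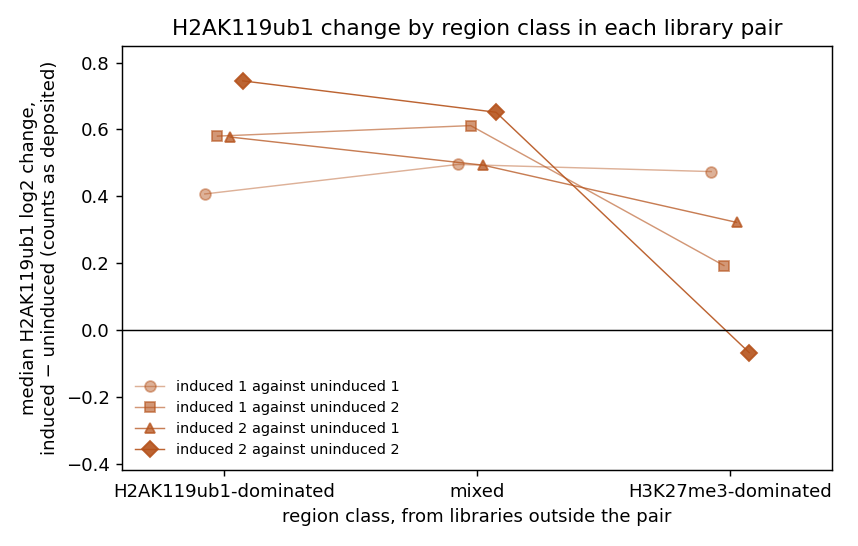
Median H2AK119ub1 log2 change (induced minus uninduced, counts as deposited) in 3 region classes taken from libraries outside the pair. Each symbol is a pair of an induced and an uninduced library, joined by a line, and the difference between the outer classes runs from −0.067 to 0.81.

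The broadest regions had the highest median of 5 width bins, a log2 change of 0.30 on the TMM scale and 0.84 on the deposited counts. Over the library pairs the TMM value ran from 0.17 to 0.44. Among these 1212 regions over 50 kb wide, 422 rose and 32 fell on the TMM scale, and 1164 rose and 17 fell on the deposited counts. The widest region, on chromosome 1 from 2965800 to 3717199 (751400 bp), rose by a log2 change of 0.57 ± 0.19 (SE, adjusted p = 0.0345), from 18248 to 27081 scaled reads. On the deposited counts its log2 change was 1.10. The region on chromosome 16 from 88664200 to 89092799 changed by 0.53 ± 0.17 (SE, adjusted p = 0.0332) and that on chromosome 12 from 132819400 to 133226399 by 0.53 ± 0.17 (SE, adjusted p = 0.0301). H3K27me3 also rose past the threshold on the TMM scale in these 3 regions (adjusted p = 0.00811, 0.00134 and 0.0249), and the difference between the marks did not pass in any (adjusted p from 0.300 to 0.465). The other two of the 5 widest, on chromosome 17 from 78991200 to 79468399 and on chromosome 19 from 1204400 to 1637599, did not pass on the TMM scale (adjusted p = 0.111 and 0.131) and did on the deposited counts. These 5 regions were chosen after their values were seen. In each of them induced replicate 2 lay above induced replicate 1 (30032 and 24129 scaled H2AK119ub1 reads in the widest). Variation between replicates in regions with many reads was not separated from the size of these rises.

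The deposited scale shifts every H2AK119ub1 change upward, and all 2777 regions that rose on the TMM scale also rose on it. Passing there is thus no separate support for a rise. Of 2397 eligible regions that rose, the 10 with the largest rise had log2 changes from 1.47 to 2.02, and all 10 also passed on the deposited counts. The largest was on chromosome 11 from 130356400 to 130357999, with 7.79 ± 2.34 scaled reads uninduced and 31.9 ± 11.95 induced (SD, n = 2 each) and a log2 change of 2.02 ± 0.42 (SE, adjusted p = 0.00295). A region on chromosome 12 from 68233400 to 68235199 rose from 9.58 to 33.2 scaled reads, and one on chromosome 4 from 16084200 to 16085799 from 9.60 to 32.8. A region on chromosome 5 from 5532600 to 5534999 rose from 13.2 to 42.8. On the X chromosome, the region from 152671600 to 152678799 rose from 38.3 ± 14.2 to 106.3 ± 15.2 scaled reads (SD, n = 2 each), with a log2 change of 1.47 ± 0.25 (SE, adjusted p = 0.000933). H3K27me3 did not pass the test in any of these 10 regions.

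Of 4862 eligible regions that fell, the 10 with the largest fall had log2 changes from −4.16 to −3.25, and all 10 passed on the deposited counts as well. On chromosome 3 from 4331000 to 4332999, H2AK119ub1 fell from 31.9 ± 3.44 to 1.67 ± 1.20 scaled reads (SD, n = 2 each), a log2 change of −4.16 ± 0.52 (SE, adjusted p = 0.000185). On chromosome 22 from 22492400 to 22494399 it fell from 47.8 to 2.93 scaled reads. On chromosome 1 it fell from 41.0 to 2.92 between 63573600 and 63575399, and from 93.6 to 9.60 between 81918200 and 81921199. The region on chromosome 7 from 92840800 to 92843199 fell from 42.9 to 3.32. In 5 of these 10 regions H3K27me3 had enough reads to be tested, and it did not pass in any.

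These H2AK119ub1 counts fell to 2944 without uninduced replicate 2 and to 3908 without induced replicate 2, with falls in the majority in both. DESeq2's Wald test called 3291 regions, and limma without a mean-variance trend called 0 at the main pseudocount, with 12355 at an unadjusted p under 0.05, and 6509 at the high pseudocount, of which 5245 were lower.

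The second comparison asked whether H3K27me3 moved with USP7. Few regions passed the test. On the TMM scale, 172 regions rose and 41 fell of 40305 tested, with 4885 at an unadjusted p under 0.05 and 2015 expected by chance. The risen regions had a median log2 change of 0.34, or 1.27-fold, and a median width of 41300 bp, and 78 of them were over 50 kb wide. Their width was not separated from the power of the test, as for H2AK119ub1. On the counts as deposited, 1 region rose and 3 fell of 40671. The median log2 change over all regions was −0.089 on the deposited counts, and the library medians of log2(count + 1) were 4.98 ± 0.032 with induction and 5.07 ± 0.030 without (SD, n = 2 each; exact two-sided permutation p = 0.333, the smallest possible). The 95% interval of the log2 change lay within 1.5-fold for 42.7% of tested regions, so for the other regions a change of that size was not excluded.

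On the TMM scale, most H3K27me3 calls went with an H2AK119ub1 call in the same direction. Among 36584 regions tested for both marks, 140 of the 169 that gained H3K27me3 also gained H2AK119ub1, where 12.4 would be shared by independent lists and 50.7 by lists independent within 50 bins of read number. Of the 33 that lost H3K27me3, 21 also lost H2AK119ub1, where 5.44 and 5.81 would be shared. Opposite calls were found in 0 regions on the TMM scale. These comparisons share no library. On the deposited counts, 3 regions tested for both had an H3K27me3 call, and 1 of these, a fall, was shared.

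Among the 165 eligible regions, the largest H3K27me3 rise was on chromosome 3 from 53077600 to 53081199, from 12.1 ± 4.63 to 33.5 ± 0.826 scaled reads (SD, n = 2 each), a log2 change of 1.46 ± 0.31 (SE, adjusted p = 0.00540). On chromosome 8 from 146125600 to 146130199 it rose from 33.9 ± 3.66 to 75.5 ± 5.99 (SD, n = 2 each; adjusted p = 0.000414), and this region also passed on the deposited counts. Among the 28 eligible regions that fell, the largest fall was on chromosome 20 from 51434800 to 51436399, from 33.9 ± 0.444 to 11.9 ± 1.21 scaled reads (SD, n = 2 each), a log2 change of −1.502 ± 0.31 (SE, adjusted p = 0.00428). On chromosome 11 from 110166400 to 110181999, H3K27me3 fell from 126.2 to 75.01 scaled reads and H2AK119ub1 from 261.1 to 96.5, and both passed. Of the 10 named rises 1 passed on the deposited counts, and of the 10 named falls 2 did.

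The number of H3K27me3 calls ran from 0 without uninduced replicate 1 to 550 without induced replicate 2, and was 4 without uninduced replicate 2 and 66 without induced replicate 1. DESeq2's Wald test called 96 regions, and the count was 0 with limma without a trend (3998 at an unadjusted p under 0.05), with all 8 libraries in 1 fit (3028) and with the uninduced libraries averaged as 1 (2025).

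The third comparison tested whether the marks responded differently, the question in the series title. The H2AK119ub1 change differed from the H3K27me3 change at 4093 of 44774 regions on the TMM scale. It was lower than the H3K27me3 change at 3628 of these and higher at 465. On the counts as deposited, it was higher at 12480 and lower at 1211 of 44949. Regions called for H2AK119ub1 were chosen on libraries that also enter the difference, so differences in the same direction were partly built in. Falls were also larger than rises (medians of 2.39-fold and 1.54-fold), so the shares below do not compare falls with rises. Among the 6391 regions where H2AK119ub1 fell, 3373 showed a difference between the marks. The median H3K27me3 log2 change over all 6391 was −0.082 (quartiles −0.23 and 0.059). Among the 2777 regions where H2AK119ub1 rose, 387 showed a difference, and the median H3K27me3 log2 change was 0.13 (quartiles 0.021 and 0.23). The count was 940 without H2AK119ub1 uninduced replicate 2 and 8767 without H2AK119ub1 induced replicate 1, and lay between 1238 and 2304 without any single H3K27me3 library. It was 1552 without H2AK119ub1 induced replicate 2, and differences in which H2AK119ub1 was lower made up the majority each time.

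Across the 45450 regions the log2 changes of both marks were weakly correlated, with Pearson r = 0.155 and Spearman rho = 0.194. These values describe regions, which are not independent replicates, and r was 0.0566 without H3K27me3 induced replicate 1 and 0.0946 without H3K27me3 uninduced replicate 1.

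**Figure D3:**
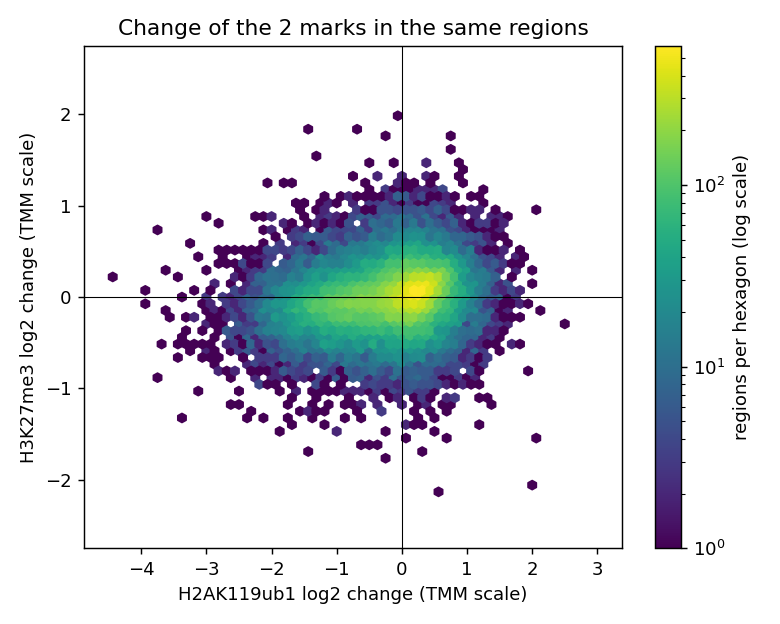
Log2 change of H2AK119ub1 (horizontal axis) and of H3K27me3 (vertical axis) in regions tested for both marks, on the TMM scale. Colour gives the number of regions per hexagon on a log scale. The H2AK119ub1 changes reach below −4, while most H3K27me3 changes lie within 1 of 0.

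The H2AK119ub1 change did not rise or fall steadily with the H3K27me3 level. From the lowest to the highest of 5 equal bins of H3K27me3 reads per kb, the median H2AK119ub1 log2 change on the TMM scale was 0.094, 0.15, −0.32, −0.32 and 0.028. On the deposited counts it was 0.62, 0.68, 0.19, 0.18 and 0.53. The third and the fourth bin were lowest. A library scale moves every region of a library by the same factor, so the same order on both scales was given in advance. The difference between the highest and the lowest bin was −0.066, less than the SD of 0.15 over library pairs.

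The changes also differed between chromosomes. On the TMM scale, the median H2AK119ub1 log2 change was highest on X (0.29), 19 (0.21) and 22 (0.19) and lowest on 5 (−0.14), and on the deposited counts it ran from 0.37 on 5 to 0.80 on X. The median H3K27me3 log2 change was also highest on X (0.11) and lowest on 5 (−0.036), and on the deposited counts it ran from −0.13 on 5 to 0.016 on X.

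**Figure D4:**
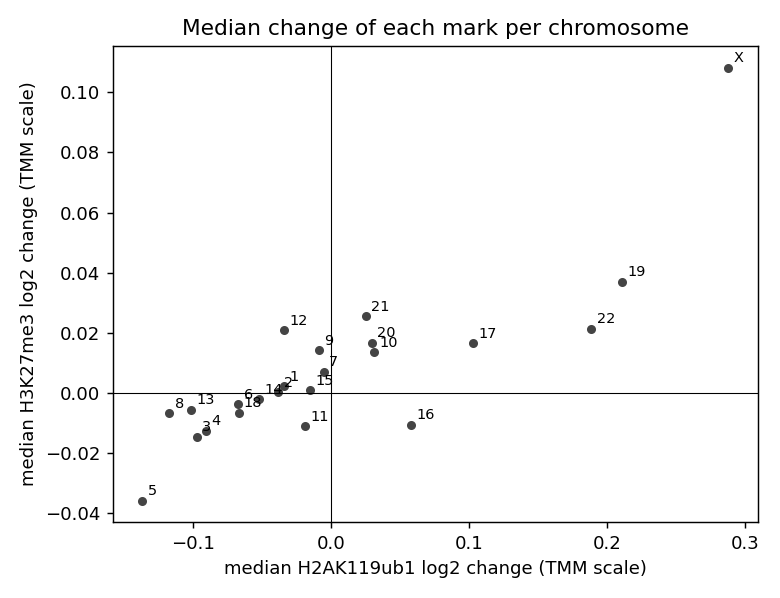
Median log2 change of H2AK119ub1 (horizontal axis) and of H3K27me3 (vertical axis) over the regions of each of 23 chromosomes, on the TMM scale. Each point is a chromosome, labelled with its name, and X lies highest on both axes.

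In the authors' deposited table, the H2AK119ub1 p was under 0.05 at 14220 regions, 13198 of them higher after induction, where chance would give 2272. In the same authors' deposited table, the H3K27me3 p was under 0.05 at 3529 regions, 822 higher and 2707 lower, where chance would give 2271. The p in the authors' deposited table was exactly 0 at 129 regions for H2AK119ub1 and 181 for H3K27me3. After Benjamini-Hochberg adjustment of the p in the authors' deposited table, with these zeros included, 176 and 182 regions passed. Of these, 47 and 1 had a p above 0. These values use counts without library scaling.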

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

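The interaction test was planned, while the tests that weigh explanations here were chosen only after the result was seen. The marks differed in their response at 4093 regions on the TMM scale, by a test of the difference itself. On the counts as deposited the number was 13691, with the opposite majority.

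The 5 largest differences towards H2AK119ub1 were a log2 of 5.63 on chromosome 1 from 174969200 to 174969799, 4.06 on chromosome 13 from 101924200 to 101924599, 3.82 on chromosome 7 from 155098000 to 155098799, 3.67 on chromosome X from 129518600 to 129519399 and 3.65 on chromosome 4 from 148200400 to 148200999. The 5 largest the other way were −6.25 on chromosome 2 from 171387000 to 171387599, −5.44 on chromosome 8 from 96146200 to 96146799, −5.12 on chromosome 12 from 125927600 to 125927999, −4.89 on chromosome 3 from 4331000 to 4332999 and −4.66 on chromosome 3 from 137338600 to 137339599. In each of these regions at least 1 of the 4 groups had a mean under 4 scaled reads, and a fitted difference with a group at 0 depends on the prior count and is no bound. On chromosome 1, H3K27me3 had a mean of 2.42 scaled reads uninduced and 0 induced. On chromosomes 2 and 8 it had 0 uninduced and 2.07 and 4.58 induced, and on chromosome 12 H2AK119ub1 had 3.59 uninduced and 0 induced.

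A higher H2AK119ub1 change in regions that it dominates than in regions dominated by H3K27me3 was weighed but did not hold in every library pair. With classes from libraries outside the pair, the smallest difference over the 4 pairs was −0.067 (log2) and the largest 0.81. Deeper sequencing of the induced libraries alone would leave no difference in any pair. Differences of up to 0.81 argue against it as the only cause in the pairs that show them. The difference was below 0 in 1 of the 4 pairs, so a response to induction is not shown by them either. A share of reads in enriched regions that varies between cultures without induction stays open. The change from the lowest to the highest 10% of regions by H2AK119ub1 density, ranked in libraries outside the ratio, was 0.34 on average after induction (pairs from −0.22 to 0.98). Between replicates (2 minus 1) it was 0.38 with induction and −0.56 without, so the larger was 0.56 in size and exceeded the average after induction. An effect of GFP-USP7 on where the mark lies was not separated from this.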

How the results depend on the processing

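The counts as deposited, TMM or total-count scales for medians, limma with trend, the crossed block, averaged H3K27me3 libraries and the level as mean log2 count were chosen after seeing the data. The cause of the shifts below was not tested, except that a library scale moves each region of a library by the same factor. For H2AK119ub1 (9168 calls, 30.3% higher), the direction of the majority reversed on the deposited counts (21578) and with libraries centred on their median (12945, of which 7637 higher). It held with total-count sizes (8101, 1324 higher) and DESeq2 size factors (9476, 3157 higher). The count was 3291 with DESeq2's Wald test, 4007 at adjusted p 0.01, and 0 with limma without trend at the main and the low pseudocount (12355 and 12006 at an unadjusted p under 0.05), against 6509 at the high pseudocount (5245 lower) and 8494 with trend. Leaving out a replicate gave 2944 to 12214.

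For H3K27me3 (213 calls), the majority reversed on the deposited counts (4) and with a 1.5-fold minimum (52, of which 25 higher). The count was 62 with centring on the median, 187 with total-count sizes (102 higher), 96 with DESeq2's Wald test and 68 at adjusted p 0.01. It was 0 with limma without trend at each pseudocount (3998, 3953 and 4223 at an unadjusted p under 0.05), in the fit of all 8 libraries (3028) and with the uninduced libraries averaged (2025). Limma with trend called 159. Leaving out a replicate gave 0 to 550.

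For the difference between the marks (4093), the majority reversed on the deposited counts (13691). Centring on the median gave 4202, of which 1762 higher. The count was 1434 with the uninduced H3K27me3 libraries averaged, 1328 at adjusted p 0.01, and 940 to 8767 without a replicate. Where leaving out a replicate left 1 library in a group, that library was assumed to vary like the others.

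The replicate numbers are shared across groups, but with 2 pairs they do not pair the samples. The correlation of same-numbered deviations was −0.187 for H2AK119ub1 and −0.0059 for H3K27me3. A replicate block gave 6928 H2AK119ub1 calls, 18 H3K27me3 calls and 1268 differences between the marks. Crossing the numbers for H2AK119ub1 gave 14202 calls.

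The median H2AK119ub1 log2 change (0.51) was 0.39 with the high pseudocount and 0.59 without the lowest 25% of regions. It reversed to −0.14 with total-count sizes and −0.0058 with TMM, and ran from 0.47 to 0.52 without a replicate. That of H3K27me3 (−0.089) reversed to 0.0026 with TMM and ran from −0.12 to −0.038 without a replicate. The correlation of the marks was 0.209 without the lowest 25% and 0.0566 to 0.205 without a replicate. The difference between the highest and lowest H3K27me3 bins (−0.066) reversed to 0.073 with 10 bins. It ran from −0.17 to 0.048 without a replicate, crossing 0 without H2AK119ub1 uninduced replicate 2 (0.00015) and induced replicate 2 (0.048). Of named-region values under alternatives, 325 of 376 for H2AK119ub1, 125 of 360 for H3K27me3 and 111 of 160 for the difference kept their call. The 0 reversals were largely built in, as extremes were named. The gene list tests and their alternatives were not run, as no hg19 annotation was used. The simulated counts had 200 changed regions at this depth. Of 1.5-fold changes, 4 of 67 were recovered for H2AK119ub1 and 12 of 67 for H3K27me3. These shares may not carry over to the data, and the part of depth in them was not tested.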

Other observations

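The tests in this part were all chosen after the result was seen. H2AK119ub1 changes were alike in nearby regions, less so with distance. Neighbouring regions less than 10 kb apart had H2AK119ub1 changes that correlated with r = 0.404 over 16961 pairs, against 0.0115 for H3K27me3. The H2AK119ub1 value was 0.315 at gaps of 10 to 50 kb, 0.145 at 50 to 200 kb and 0.0673 at 200 to 1000 kb. These are correlations across regions, which are not independent replicates. They were not computed between replicates, so regional variation between libraries was not separated from a response to induction. Few H3K27me3 regions passed the test, and its low r was not separated from noise in small changes. Among 491 windows of 5 Mb with at least 20 regions, the lowest median log2 change on the TMM scale was −1.09, on chromosome 1 from 100 to 105 Mb, where 23 of 50 regions fell and 0 rose. The highest was 0.48, on chromosome 10 from 130 to 135 Mb, where 48 of 186 regions rose and 7 fell. On the deposited counts these medians were −0.60, with 14 regions that fell and 5 that rose, and 1.00, with 1 that fell and 134 that rose. These windows are the extremes of 491, and the range expected without change was not tested.

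The changes differed with distance to the nearer chromosome end, but distance was not separated from chromosome. Only long chromosomes hold regions beyond 50 Mb from both ends, and the medians also differed between chromosomes (0.21 on 19 and −0.14 on 5, H2AK119ub1, TMM scale). The median H2AK119ub1 log2 change was 0.32 within 2 Mb of an end, 0.15 at 2 to 10 Mb, −0.034 at 10 to 50 Mb and −0.17 beyond 50 Mb on the TMM scale, and 0.85, 0.67, 0.48 and 0.34 on the deposited counts. For H3K27me3 it was 0.075, 0.030, −0.0029 and −0.021 on the TMM scale, and −0.017, −0.062, −0.095 and −0.11 on the deposited counts.

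A different DNA copy number in induced and uninduced cells would shift both antibodies alike. The end minus interior difference of H2AK119ub1 exceeded that of H3K27me3 by at least 0.17 in the 4 library pairs. This argues against copy number as the only cause. The H3K27me3 difference was 0.095 (pairs from 0.031 to 0.15), so a part of that kind, shared by both marks, is not excluded. More H2AK119ub1-dominated regions near the ends were weighed as well. The H2AK119ub1 difference was at least 0.20 in each class and pair, with classes from libraries outside the pair. These classes are coarse, so a different make-up within a class is not excluded. Neither chromosome nor width was held fixed, and median widths were 5400 bp within 2 Mb of an end and 2200 bp beyond 50 Mb. A bias shared by the induced libraries of both antibodies, such as base composition, may contribute, also to the regions called for both marks. The chromosome medians of both changes correlated over 23 chromosomes with Pearson r = 0.837 and Spearman rho = 0.778, and r was 0.695 without X and 19. The permutation p was 1e-05 for each, the smallest that 100000 permutations can give, and 1e-05 after adjustment over these 2 measures. The permutations shuffle chromosomes, which all come from the same libraries, so this p does not measure variation between cultures. Base composition itself was not measured, and an effect of GFP-USP7 on both marks in the same chromosomes stays open too.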
